A study of Oryza sativa with 6 samples.

How the data were processed

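Endosperm RNA of field-grown rice at 9 days after flowering was hybridized by the submitters to 6 Affymetrix rice arrays, 3 of wild type Dongjin and 3 of osbzip58-1, from 0.5 ug of total RNA per sample, labelled with biotin by a 3' in vitro transcription kit. The series describes the arrays of each group as independent biological replicates. The deposited values are log2 MAS5 signals per probe set; the authors name MAS5 without a version, a scaling target or a floor. The values themselves show that each array was scaled to the same mean signal (500.1 after trimming 2%), that signals under 1 stand at 0, and that no detection calls are given. Group and replicate number were taken from the source names. The titles number the osbzip58-1 arrays differently, and neither numbering was used to pair samples.

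The deposited log2 values were used as they are, with no further normalization. The 123 control and 64 reporter probe sets were kept apart from the 57194 rice probe sets. The plan named rice probe sets, but a first exploratory run had counted the reporter probe sets among them, so this separation was made after their values had been seen; the result with them is given as an added alternative. A rice probe set was tested if its signal was at or above the 40th percentile of that array's rice probe sets on at least 3 of 6 arrays, which left 34883. osbzip58-1 was compared with wild type by limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Unless an alternative is named, the adjusted p of a gene comes from this limma fit, and the error of a fold change is its SE. Where all arrays of 1 group lay under the 40th percentile, the fold was computed against that percentile, or the array's own value if higher, and is given as a lower bound. Single array-level measures were compared by exact two-sided permutation tests, whose smallest p with 3 arrays against 3 is 0.1. On simulated arrays with 200 changed probe sets, the fit recovered 0% of log2 changes of 0.5, 19.0% of changes of 1 and 57.5% of changes of 2, with 0, 1 and 3 false calls. The simulated noise was normal and independent between probe sets. The real arrays gave 2209 calls, with absolute log2 fold changes down to 0.34, so the simulated rates do not carry over to them.

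Probe sets were paired with genes through the platform's probe table and the RefSeq gene table of assembly ASM3414082v1. A single gene was listed for 22436 rice probe sets, several for 95 and none for 34663. The 17905 genes were all found in the RefSeq table, and 2448 of them have a name beyond a LOC identifier. No table names OsbZIP58. The probe set of LOC4342570 was selected for that gene before its values were seen, from memory of its source sequence, which nothing in the tables backs, so its values are reported for LOC4342570 alone.

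The test, the filter, the gene lists, the rule for named genes and the alternatives of the analysis plan were fixed before the data were examined. Named genes were the mutated gene, the 10 highest and 10 lowest log2 fold changes among probe sets past the threshold with groups that did not overlap and 1 named gene, up to 4 members of each list with the smallest adjusted p (or the 2 with the largest absolute log2 fold change where fewer than 2 passed), and the 6 reported promoter targets. For the lists each gene was represented by its probe set with the highest mean signal, and for the highest and lowest genes by the first-ranked one, so PROLM25 appears with both of its probe sets. The 11 lists hold 145 entries, of which 71 different genes were measured. Lists with at least 5 measured genes were tested by camera with a preset correlation of 0.01, then with an estimated one, and by fry, whose p tests whether a list's genes move on balance in 1 direction without comparing them with other genes. Adjustment was over the 9 lists tested. A further 16 lists planned by gene description were not run, since the tables used hold no descriptions. In their place 29 families were defined by gene symbol after the annotation and the array-level values had been seen and before any gene's value was.

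The alternatives fixed beforehand were no filter, a 60th percentile filter, quantile normalization, median centring, an offset of 11.2 signal units before the log, no intensity trend, array weights, replicate or title number as a block, an ordinary equal-variance test per probe set, the mean of a gene's probe sets, a threshold of 0.01 and leaving out each array. Scaling to the 9 spiked bacterial controls, the inclusion of the reporter probe sets and all alternatives for the families were added after seeing the data. The tests of PROLM25 and SSI against a shift of bright probe sets first used quantile normalization alone. The condition that they also pass under spiked control scaling was added when both values were known, and the label of SSI went from excluded to open. The same test of SSIIc was dropped, since its signal lies between 8 and 10, where the median log2 fold change was 0.06. Lists were also set against 10000 random lists matched on mean signal. statmod 1.5.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.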

Results

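Transcript levels were measured on Affymetrix rice arrays in endosperm, the starch-storing tissue of the grain, harvested at 9 days after flowering. The arrays fell into 2 groups: wild type Dongjin (n = 3), a japonica rice cultivar, and osbzip58-1 (n = 3), a mutant line in the Dongjin background named after the gene of the transcription factor OsbZIP58. Each array carried 57381 probe sets: 57194 for rice sequences, 64 for reporter genes and 123 controls. The median log2 signal of the rice probe sets lay between 5.61 and 5.91 on the 6 arrays, and on average 320 ± 178 values per array stood at 0 in wild type and 725 ± 216 in osbzip58-1 (SD, n = 3 per group, groups not overlapping, exact permutation p = 0.1, the smallest possible). Array data have no read depth, so the number of arrays limits the precision. Pairs of arrays within a group correlated across the tested probe sets with r between 0.930 and 0.938, and pairs between groups with r between 0.912 and 0.920. Genes are not independent replicates in these correlations. The first principal component held 30.5% of the variance and separated the groups. The second component held 19.2% and cut across them, with wild type replicate 2 and osbzip58-1 replicate 3 at -75.0 and -73.6 and the other arrays between 20.1 and 61.5.

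The comparison of osbzip58-1 with wild type asks which endosperm transcripts differ in the mutant, with the mutated gene first. The annotation tables gave no probe set the name OsbZIP58, so no value is reported under that name. LOC4342570, whose probe set was selected before its values were seen, had the lowest fitted log2 fold change of all tested probe sets. Its log2 signal was 13.59 ± 0.11 (SD, n = 3) in wild type and 2.57 ± 0.84 (SD, n = 3) in osbzip58-1, where it lay under the 40th percentile on every array. The transcript was at least 392-fold lower in osbzip58-1. The fitted log2 fold change of -11.02 (SE 0.36, limma adjusted p = 1.67e-06) is taken against osbzip58-1 values not above background, so the bound is the measure of its size. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow.

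Only 2793 of the 34883 tested probe sets had a named gene, and larger changes lay outside them. LOC4331398 had log2 fold changes of 6.75 and 6.07 on its 2 probe sets (adjusted p = 0.00310 and 0.00467). Its wild type arrays spread widely (SD 2.19 on each). LOC4338121 had -4.73 (adjusted p = 5.59e-06). Among genes with a name in the tables, IPA1, a squamosa promoter-binding transcription factor that shapes plant architecture, rose from a log2 signal of 6.07 ± 0.49 to 9.49 ± 0.09 (SD, n = 3 per group), a 10.7-fold difference (adjusted p = 0.000255). BiP4, a chaperone of the endoplasmic reticulum, rose 4.68-fold, and METK3, an S-adenosylmethionine synthetase, rose 4.35-fold. JAZ9, a repressor of jasmonate signalling, rose 4.32-fold. PROLM25, a prolamin storage protein, fell from 15.41 ± 0.08 to 12.06 ± 0.72 (SD, n = 3 per group), a 10.1-fold difference (adjusted p = 0.000524), and its other probe set had a log2 fold change of -2.95. ABA8OX2, an enzyme of abscisic acid breakdown, had a log2 fold change of -1.66 (SE 0.12, adjusted p = 0.000251).

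Among the other named genes with high fitted log2 fold changes were CSLH1, a cellulose synthase-like protein, at 3.49 (SE 0.87, adjusted p = 0.0463), and Nramp1, a metal transporter, at 3.37 (SE 0.80, adjusted p = 0.0380). The value of Nramp1 was 2.78 without wild type replicate 3. Both lay under the 40th percentile on every wild type array, so these fitted values and their rank are not measured against a signal above background, and the differences were at least 2.24-fold for CSLH1 and at least 2.67-fold for Nramp1. The signals of pinA, CH16 and RBBI3.3, a Bowman-Birk proteinase inhibitor, were 6.24-fold, 6.18-fold and 5.65-fold higher, and their osbzip58-1 arrays spread widely (SD 1.41, 1.58 and 1.31). Their log2 fold changes of 2.64, 2.63 and 2.498 moved to 1.83, 3.35 and 1.77 without osbzip58-1 replicate 1, and that of CH16 to 1.78 without osbzip58-1 replicate 3. RTEL1, a DNA helicase, had 2.28 on 1 probe set and 0.11 on its other. Among the lowest, IAA7, a repressor of auxin responses, had a log2 fold change of -2.61. Its osbzip58-1 signals were 4.58, 5.18 and 5.41, near the 40th percentiles of 4.83, 4.94 and 5.16, so this size is uncertain too. The copper transporters COPT2 and COPT1 had -2.18 and -1.45. CKX5, an enzyme of cytokinin breakdown, had -1.88, ARGOS, a regulator of organ size, had -1.78, and the aquaporin PIP2-5 had -1.72. R1623 had -1.61, with a range of -1.61 to -0.02 over its 3 probe sets, and BBD1 had -1.42. By the rule that selected them, the 10 genes of each direction had an adjusted p under 0.05 and groups that did not overlap.

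**Figure D1:**
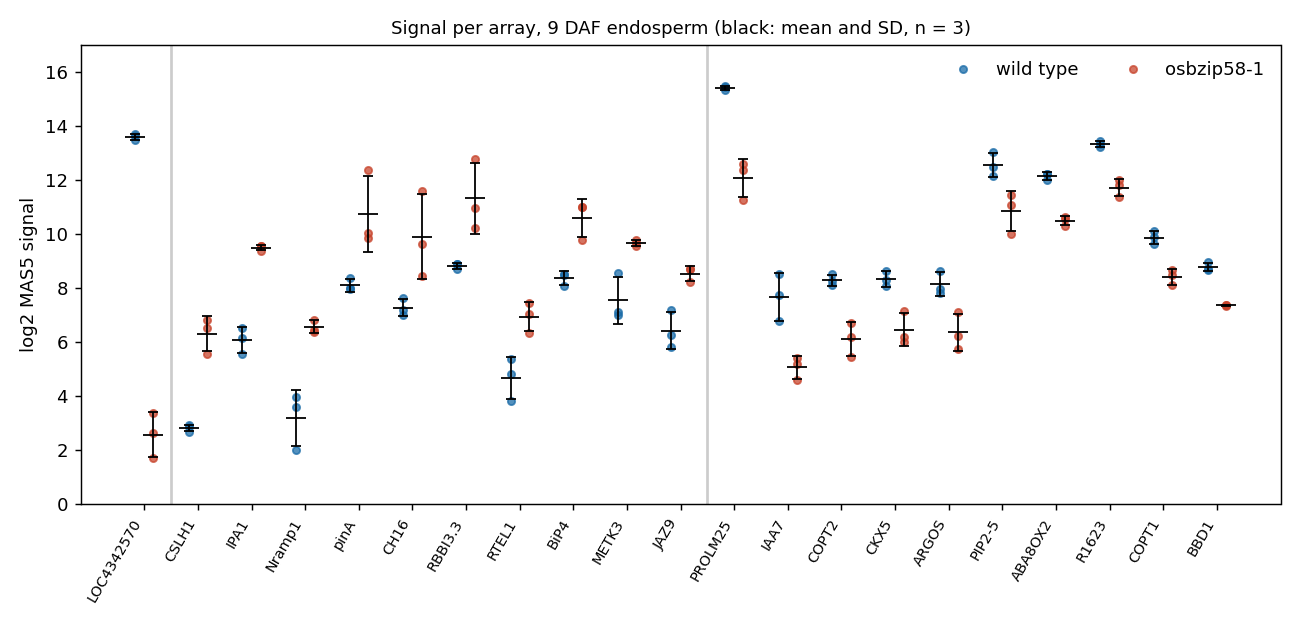
Log2 signal on each array for LOC4342570 and the named genes with the 10 highest and 10 lowest log2 fold changes, wild type and osbzip58-1 apart, with the mean and SD of 3 arrays. LOC4342570 lies at 13.59 in wild type and 2.57 in osbzip58-1, PROLM25 at 15.41 and 12.06, and IPA1 at 6.07 and 9.49.

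Of 34883 tested probe sets, 2209 (6.33%) changed between the groups at an adjusted p under 0.05 by limma, 1116 of them higher and 1093 lower in osbzip58-1. A log2 fold change of 1 or more in either direction was reached by 733, of which 426 were higher and 307 lower. At an unadjusted p under 0.05 there were 7503, against 1744 expected by chance, and the groups did not overlap for 27.7% of probe sets, where chance gives 10%. Of the changed probe sets, 292 belonged to 267 named genes. The share that was higher, 50.5%, depended on the scaling: it was 36.4% after centring each array on its median, and 96.0% of 9742 calls when the arrays were scaled to spiked bacterial controls, which moved the median of all probe sets by 0.41. Without an intensity trend in the variance, 99 probe sets passed. Of the 37 called probe sets reported here for genes with a name, 5 still passed. These were CSLH1, IPA1, ABA8OX2, BBD1 and the brightest probe set of PROLM25 (adjusted p = 0.0491). The rest lost their calls, among them the other PROLM25 probe set, at a log2 fold change of -3.34 (adjusted p = 0.0560). Without single arrays between 543 (wild type replicate 3) and 1617 (osbzip58-1 replicate 1) passed, with 903 without wild type replicate 1, 1237 without wild type replicate 2, 1264 without osbzip58-1 replicate 2 and 1413 without osbzip58-1 replicate 3. Leaving out single arrays ended the calls of CSLH1 (any array, adjusted p up to 0.228), Nramp1 (any but wild type replicate 1, up to 0.163), RTEL1 (any but wild type replicate 2, up to 0.150), ARGOS (any but osbzip58-1 replicate 2, up to 0.118), CH16 (any wild type array or osbzip58-1 replicate 2, up to 0.128), pinA and RBBI3.3 (any wild type array, up to 0.0952 and 0.0890), IAA7 and PIP2-5 (wild type replicate 2 or 3, up to 0.0807 and 0.0760) and CKX5 (wild type replicate 1 or 3, up to 0.0614).

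The brightest transcripts had lower signal in osbzip58-1 as a class. The 429 probe sets with a mean log2 signal of 14 and over had a median log2 fold change of -0.31, with 103 lower and 2 higher, while the medians of the classes from 6 to 14 lay between -0.07 and 0.06. The 9202 probe sets under 6 had a median of -0.10. The 9 spiked bacterial controls, which the standard protocol adds in equal amounts, averaged 12.19 ± 0.02 in wild type and 11.79 ± 0.06 in osbzip58-1 (SD, n = 3 per group), a difference of -0.40 with exact permutation p = 0.1. Their single differences ranged from -0.49 to -0.32, at wild type means from 9.86 to 15.17. Rice probe sets of 8 to 10 and of 10 to 12 had medians of 0.06 and 0.02. The controls were thus lower at all their signal levels, unlike the rice probe sets. The 100 brightest probe sets held 9.01% of the signal in wild type and 7.37% in osbzip58-1. Ribosomal RNA probe sets averaged 12.82 ± 0.27 and 13.54 ± 0.31.

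**Figure D2:**
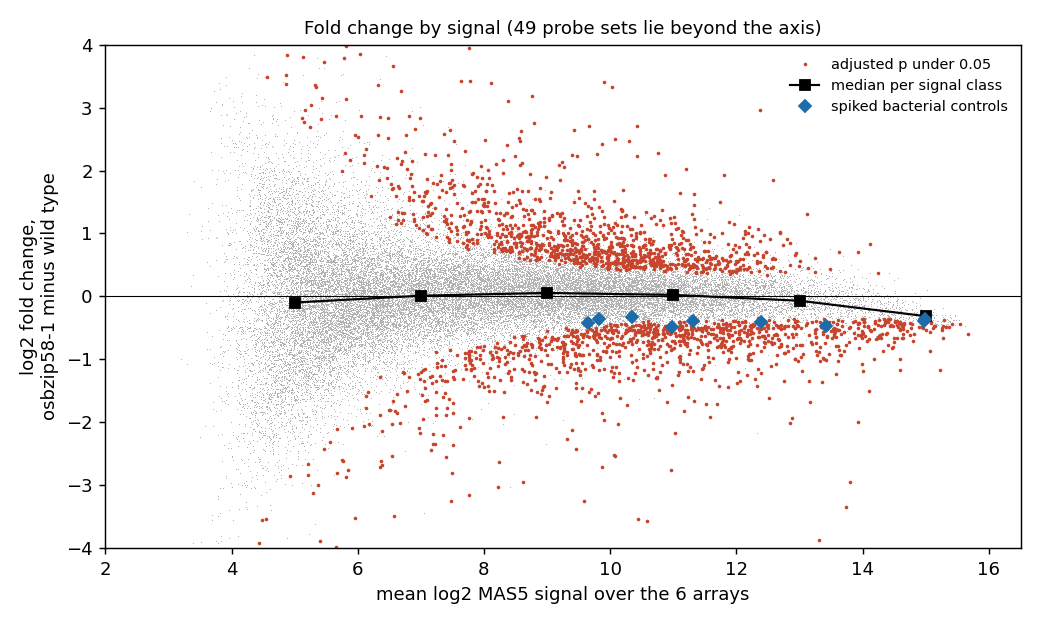
Log2 fold change (osbzip58-1 minus wild type) of each tested probe set against its mean log2 signal, with the median of each signal class and the 9 spiked controls marked. The class of 14 and over lies at -0.31 and the spiked controls average -0.40, while the classes from 6 to 14 lie between -0.07 and 0.06 and the class under 6 at -0.10.

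Among the starch synthesis genes, SSI, a soluble starch synthase, fell from 14.23 ± 0.14 to 13.62 ± 0.09 (SD, n = 3 per group), a 1.53-fold difference (adjusted p = 0.0104). SSIIc, another starch synthase, fell 1.54-fold (adjusted p = 0.0251), and SBE1, a starch branching enzyme, fell 1.39-fold (adjusted p = 0.0367). Of 9 measured genes 0 rose, 3 fell and 6 did not pass; adjusted over the list alone, 1 rose and 5 fell. The list's median log2 fold change was -0.35, but 0.05 when scaled to the spiked controls, with the median of all probe sets then at 0.41. The list passed camera (adjusted p = 0.0226) and fry (adjusted p = 0.0124), and camera gave adjusted p = 0.217 with an estimated correlation. The camera call ended after quantile normalization (median -0.03, adjusted p = 0.763), under spiked control scaling (adjusted p = 0.0946) and without osbzip58-1 replicate 3 (median -0.39, adjusted p = 0.0625). Bright probe sets at 14 and over had a median of -0.31, but the list also holds dimmer genes. Random lists matched on signal had a median of -0.19, and the list lay at percentile 4.91 of them. The call of SSI ended without wild type replicate 3 (adjusted p = 0.0655), that of SSIIc without any array but wild type replicate 2 (up to 0.0909) and that of SBE1 without any array but osbzip58-1 replicate 2 (up to 0.157). After quantile normalization SBE1 had -0.05 (adjusted p = 0.711), while SSI had -0.40 (adjusted p = 0.0332) and SSIIc -0.68 (adjusted p = 0.0217). Under spiked control scaling SSI had -0.21, SSIIc -0.22 and SBE1 -0.07, with none past the threshold. Without an intensity trend SSI, SSIIc and SBE1 lost their calls too (limma adjusted p = 0.124, 0.124 and 0.192).

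Promoters reported to be bound by OsbZIP58 belong to 6 genes of the starch list, of which the tables name 3 on the array. SBE1 fell as given, with 6 probe sets between -1.20 and -0.26, 2 of them past the test. Wx, the granule-bound starch synthase that makes amylose, had a log2 fold change of -0.41 (SE 0.12, adjusted p = 0.0789) on its brightest probe set, and 1 of its 5 probe sets passed. Without osbzip58-1 replicate 2 it had -0.54 (adjusted p = 0.0340), and after quantile normalization 0.0028 (adjusted p = 0.987). SSIIa, a starch synthase of amylopectin, had -0.23 (SE 0.12, adjusted p = 0.305) on its brightest probe set and a positive value that did not pass on its other. AGPL3, BEIIb and ISA2 were not named in the tables. Of the 3 measured genes 1 fell, and 2 fell adjusted over the list alone; the list was chosen by the study on this mutant, so this count is not independent evidence.

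Seed storage proteins, which fill the protein bodies of the endosperm, included the lowest log2 fold change of the named genes that passed the test. PROLM25 fell 7.72-fold on its brightest probe set (15.27 ± 0.05 to 12.32 ± 0.58, SD, n = 3 per group, adjusted p = 0.000357). GluA1, a glutelin, fell 1.52-fold (adjusted p = 0.0220). Of 9 measured genes 0 rose, 2 fell and 7 did not pass; adjusted over the list alone, 9 fell. The median log2 fold change was -0.41, against -0.31 for all probe sets of 14 and over. The list passed camera (adjusted p = 1.65e-06) and fry (adjusted p = 0.0252), and camera gave adjusted p = 0.217 with an estimated correlation. After quantile normalization the list's median was -0.03 (adjusted p = 0.392), with PROLM25 at -2.73 (adjusted p = 0.000929) and GluA1 at -0.12 (adjusted p = 0.382); under spiked control scaling the median was -0.0036 and the list passed camera (adjusted p = 4.97e-06), with PROLM25 at -2.55 (adjusted p = 0.000250) and GluA1 at -0.20 (adjusted p = 0.191). The call of GluA1 also ended without wild type replicate 1 or 3 (adjusted p up to 0.1).

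Chaperones of the endoplasmic reticulum, where storage proteins fold, moved in both directions. BiP4 rose from 8.35 ± 0.26 to 10.58 ± 0.70 (SD, n = 3 per group, adjusted p = 0.00474). PDIL2-3, a protein disulfide isomerase, fell 1.42-fold (adjusted p = 0.0119), and BiP1, the main chaperone of this compartment, fell 1.42-fold (adjusted p = 0.0268). Of 8 measured genes 1 rose, 2 fell and 5 did not pass; adjusted over the list alone, 1 rose and 5 fell. The median was -0.30 and the mean 0.05, which differ in sign, and the camera direction was down. The list did not pass camera (adjusted p = 0.0650, and 0.217 with an estimated correlation) and passed fry (adjusted p = 0.00416). It passed camera without osbzip58-1 replicate 1 (adjusted p = 0.0469), and its median was 0.10 under spiked control scaling. PDIL2-3 and BiP1 lost their calls after quantile normalization (log2 fold changes -0.27 and -0.11), under spiked control scaling (-0.11 and -0.10) and without wild type replicate 1 or 3, BiP1 also without wild type replicate 2 (adjusted p up to 0.0584 and 0.126).

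In sugar supply and plastid import, SUS1, a sucrose synthase, rose 1.90-fold (9.47 ± 0.33 to 10.40 ± 0.31, SD, n = 3 per group, adjusted p = 0.0278), with both of its probe sets past the test. CIN2, a cell wall invertase, had a log2 fold change of -0.50 (adjusted p = 0.0850). Of 7 measured genes 1 rose, 0 fell and 6 did not pass; adjusted over the list alone, 1 rose and 1 fell. The median was -0.06 and the mean 0.03, which differ in sign, and camera gave adjusted p = 0.792; the median was 0.21 after quantile normalization and 0.34 under spiked control scaling. The call of SUS1 ended without wild type replicate 1 or 2 or osbzip58-1 replicate 1 or 2 (adjusted p up to 0.0858), and CIN2 passed without osbzip58-1 replicate 2 (adjusted p = 0.0313).

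Of the amylases, which degrade starch, 3 were measured and 0 passed, so the list was not tested. RAmy3D had a log2 fold change of 2.36 (SE 1.96, adjusted p = 0.534) and RAmy3E -0.91 (SE 1.14, adjusted p = 0.693), both with arrays that spread widely within the groups. Without single arrays RAmy3D ranged from 0.76 (without osbzip58-1 replicate 2) to 4.66 (without osbzip58-1 replicate 3), with 0.90 without wild type replicate 2, 3.23 without wild type replicate 1 and 1.64 without osbzip58-1 replicate 1. RAmy3E was -2.14 without osbzip58-1 replicate 2 and turned to 0.75 without osbzip58-1 replicate 1, so its direction rested on that array. Adjusted over the list alone, 0 passed. Among 5 endosperm transcription factors 0 passed; adjusted over the list alone, 2 rose and 1 fell. RSR1, a regulator of starch synthesis, had -1.10 (SE 0.37, adjusted p = 0.115) and MADS6 had 0.77 (SE 0.30, adjusted p = 0.167). The median of the factors was 0.09, the mean 0.01, and camera gave adjusted p = 0.796. RSR1 and MADS6 passed without osbzip58-1 replicate 3 (adjusted p = 0.0485 and 0.0424), and MADS6 under spiked control scaling (adjusted p = 0.0207).

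DNA replication genes had higher signal in osbzip58-1. MCM2, a subunit of the replicative helicase, rose 2.09-fold (9.10 ± 0.22 to 10.17 ± 0.25, SD, n = 3 per group, adjusted p = 0.00884). The helicase subunits MCM4 and MCM7 rose 2.42-fold and 2.07-fold (adjusted p = 0.0160 and 0.0390), and MCM5 rose 2.05-fold at the edge of the threshold (adjusted p = 0.0499). Of 9 measured genes 4 rose, 0 fell and 5 did not pass; adjusted over the list alone, 9 rose. The median log2 fold change was 1.05, 0.98 after quantile normalization and 1.45 under spiked control scaling. The list passed camera (adjusted p = 1.88e-05) and fry (adjusted p = 0.0207), and camera gave adjusted p = 0.217 with an estimated correlation. The calls of MCM7 and MCM5 ended without any 1 of the 6 arrays (adjusted p up to 0.107 and 0.141) and without the filter, that of MCM4 without wild type replicate 1 (adjusted p = 0.0584), and that of MCM5 after quantile normalization (adjusted p = 0.0706). Without an intensity trend MCM2, MCM4, MCM7 and MCM5 all lost their calls (limma adjusted p = 0.103, 0.121, 0.125 and 0.193). They also lost them with the title number as a block and in the ordinary test per probe set.

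Heat shock genes had lower signal in osbzip58-1. HSP17.9A, a small heat shock protein, fell 1.77-fold (14.88 ± 0.05 to 14.05 ± 0.06, SD, n = 3 per group, adjusted p = 0.00163). HSP26.7, a further small heat shock protein, fell 1.58-fold (adjusted p = 0.0124), HSP101, a disaggregating chaperone, fell 1.56-fold (adjusted p = 0.0150), and HSP16.9A fell 1.47-fold (adjusted p = 0.0210). Of 8 measured genes 0 rose, 4 fell and 4 did not pass; adjusted over the list alone, 7 fell. The median was -0.64, against -0.31 for all probe sets of 14 and over, -0.35 after quantile normalization and -0.24 under spiked control scaling. The list passed camera (adjusted p = 1.65e-06) and fry (adjusted p = 0.00963), and camera gave adjusted p = 0.217 with an estimated correlation. HSP26.7 and HSP16.9A did not pass after quantile normalization (log2 fold changes -0.34 and -0.23), HSP26.7, HSP101 and HSP16.9A did not pass under spiked control scaling (-0.25, -0.24 and -0.15) or without wild type replicate 3 (adjusted p up to 0.0751, 0.0820 and 0.0821), and HSP16.9A did not pass without wild type replicate 1 or 2. Without an intensity trend HSP17.9A, HSP26.7, HSP101 and HSP16.9A all lost their calls (limma adjusted p = 0.0702, 0.132, 0.139 and 0.158).

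Markers of other grain tissues were measured as a background. Of 8 embryo and aleurone markers, VP1, a transcription factor of seed maturation, fell 1.44-fold (adjusted p = 0.0394), and 0 rose; adjusted over the list alone, 2 fell. RAB16A, a dehydrin, had a log2 fold change of -0.77 (SE 0.37, adjusted p = 0.273). The median was -0.04 and camera gave adjusted p = 0.272. Of 5 green tissue markers 0 passed, also adjusted over the list alone; CAB2R, a chlorophyll-binding protein, had -0.37 (adjusted p = 0.144) and RCA, rubisco activase, had -0.17 (adjusted p = 0.411). Their median was -0.17, and camera gave adjusted p = 0.268, but 0.0334 without wild type replicate 2. The call of VP1 ended without any 1 of the 6 arrays (adjusted p up to 0.106), and under spiked control scaling it had -0.13 (adjusted p = 0.484), with the medians of both marker lists above 0 (0.36 and 0.24), as they were after quantile normalization (0.03 and 0.02).

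**Figure D3:**
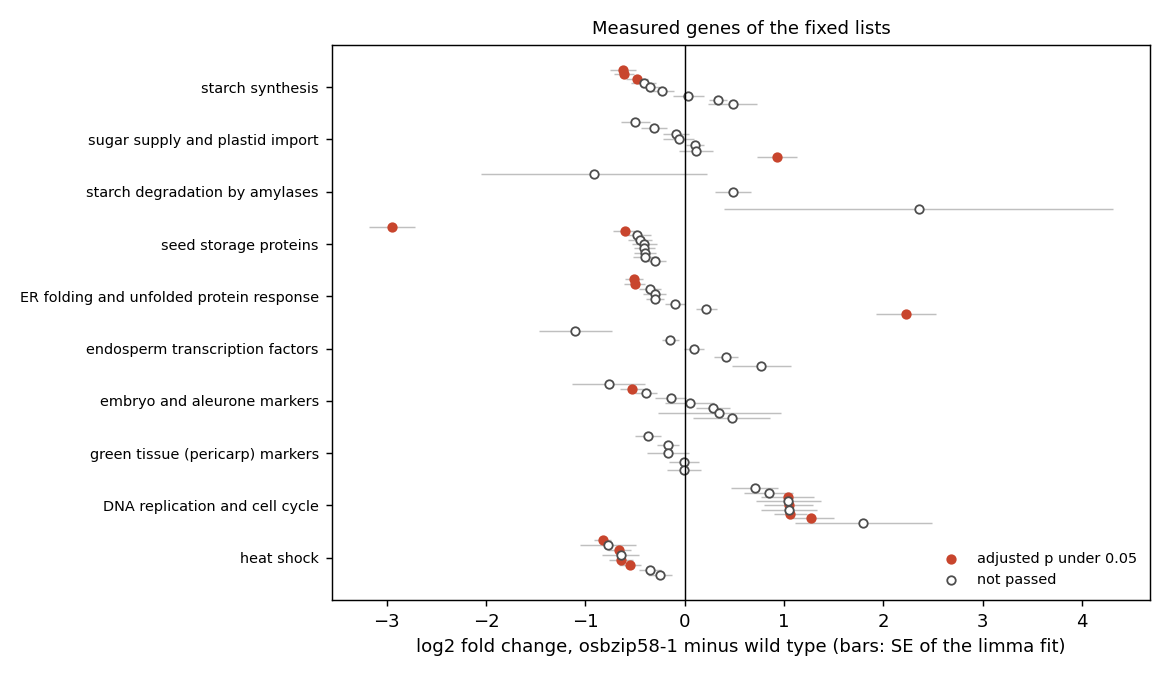
Log2 fold change (osbzip58-1 minus wild type, with the SE of the limma fit) of the measured genes of 10 lists, filled where the adjusted p was under 0.05. DNA replication genes lie to the right with a median of 1.05, heat shock and storage protein genes to the left with medians of -0.64 and -0.41, and PROLM25 stands apart at -2.95.

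Across the lists, 71 genes were measured and 18 changed. Of 9 lists tested by camera 4 passed with the preset correlation and 0 with an estimated one, and 5 passed fry.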

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

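The tests of a mixed sample, of the reporter background, of tissue contamination and of PROLM25 and SSI after quantile normalization, as well as spiked control scaling, were chosen after the results were seen; the patterns themselves were noticed in these data.

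Of the 64 reporter probe sets, which are outside the main comparison, 2 were bright in osbzip58-1 and dim in wild type. Their mean log2 signals in osbzip58-1 were 14.52 ± 0.08 and 14.58 ± 0.13 (SD, n = 3), against 2.64 ± 1.90 and 4.78 ± 1.03 in wild type, and the first was at least 669-fold higher. Every osbzip58-1 array lay above every wild type array, by at least 8.65, which argues against a mislabelled array. The 2 probe sets were noticed for this very difference. A share of wild type RNA in an osbzip58-1 array would lower such high signals only a little, so these values cannot decide on that kind of mixing. The other 62 reporter probe sets had a median difference of -0.12, which argues against a general background difference. A candidate explanation is reporter or marker sequence carried by the osbzip58-1 line, which no value here tests.

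The starch synthesis, storage protein and heat shock lists were lower in osbzip58-1, with medians of -0.35, -0.41 and -0.64. Bright probe sets were lower too, and spiked controls were lower at all their signal levels. Among random lists matched on signal, the heat shock median lay at percentile 0, and PROLM25 had -2.73 after quantile normalization (-2.95 before) and -2.55 under spiked control scaling, each past the threshold, which argues against a shared shift of bright probe sets as the whole cause for these. SSI passed after quantile normalization at -0.40 and not under spiked control scaling at -0.21 (adjusted p = 0.141). The starch and storage protein medians lay at percentiles 4.91 and 8.25. For these medians a shift shared by bright probe sets stays a candidate explanation. SSI averaged 14.23 in wild type and 13.62 in osbzip58-1, and probe sets of 12 to 14 had a median of only -0.07. Spiked control scaling moves all signals of an array alike, so it cannot test a shift of bright probe sets alone. The question is left undecided for SSI. Scaling each array to the same mean multiplies all its signals by a single factor. That step alone cannot lower the class of 14 and over (median -0.31) and leave that of 8 to 10 at 0.06. A lower share of abundant endosperm transcripts in the mutant would lower the brightest probe sets too, and for heat shock genes an effect of the mutation and a difference in field temperature at harvest stay open, all untested.

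DNA replication genes were higher in osbzip58-1, with a median of 1.05. The median lay at percentile 100 of random lists matched on signal, which argues against a shift shared by probe sets of this signal. RNA from embryo, aleurone or green outer tissue would raise the markers of those tissues, whose higher list median was -0.044; the levels of these markers in wild type were already high (list medians 12.53 and 13.60), which would hide a small share, so this source cannot be told apart from a change within the endosperm. A difference in developmental stage or cell number of the mutant endosperm stays open and untested.

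Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For the changed probe sets 1 split, the real one, gave a count as large, with 2209 against a highest other count of 0. Each other split mixes the lines, so any difference between them widens the spread within its groups. The count of 0 is therefore not a chance level. For the lists called by camera 2 splits gave a count as large, with 4 in the real split and 6 in the highest other. The splits that mix the lines called 0, 3, 3, 3, 2, 2, 2, 6 and 2 lists. Camera with the preset correlation thus called lists in most groupings that mix the lines as well, so passing it is weak evidence for a list.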

How the results depend on the processing

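Spiked control scaling, the inclusion of the reporter probe sets and the alternatives run on the families were chosen after the results were seen. LOC4342570 stayed past the threshold under all 18 alternatives run on it, with fitted values between -11.42 and -9.45 and adjusted p up to 0.0422, the highest being that of the ordinary test per probe set. Of 842 values of 47 probe sets of named genes under alternatives, 628 kept their direction and side of the threshold, 202 were no longer past it and 5 came past it. Another 7 changed sign, of which 0 were past the threshold in either setting: after quantile normalization CAB2R had 0.023, RCA 0.0085 and Wx 0.0028, under spiked control scaling CAB2R had 0.033, RCA 0.23 and SSIIa 0.17, and RAmy3E ran from -2.14 to 0.75 without single arrays, positive without osbzip58-1 replicate 1. The heat shock and DNA replication lists passed camera under all 18 alternatives run on them (medians from -0.71 to -0.24 and from 0.84 to 1.45), all of which used the preset correlation; with an estimated correlation neither passed (adjusted p = 0.217 for each).

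The counts in this order are changed, higher, lower, changed by a log2 fold change of 1 or more, and changed genes of the lists. They were 2209, 1116, 1093, 733 and 18 as reported, 99, 49, 50, 99 and 1 without an intensity trend, 536, 262, 274, 435 and 3 with the title number as a block, and 48, 26, 22, 21 and 1 with the ordinary test per probe set. At a threshold of 0.01 the first 4 were 489, 207, 282 and 287, and under spiked control scaling 9742, 9353, 389 and 2305, from a shift of the median of all probe sets to 0.41. Without single arrays they ranged from 543 to 1617, 270 to 792, 273 to 825, 346 to 624 and 6 to 19, and the lists called from 3 to 5. The lowest total, 543, was without wild type replicate 3. Quantile normalization left 2 lists called. Fewer arrays lower the power by construction, and the stricter threshold cuts the count by construction. With the title number as a block, titles carried by a single array drop out of the comparison, which also lowers the power. The other causes were not tested.

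Under spiked control scaling the medians of starch synthesis (0.054), ribosomal proteins (0.21), small heat shock proteins (0.052), thioredoxins and glutaredoxins (0.30), sugar supply (0.34), endoplasmic reticulum folding (0.10), embryo and aleurone markers (0.36) and green tissue markers (0.24) turned positive, by the construction of that scaling. The medians of lists that had not passed camera also changed sign elsewhere, with 0 of them past it there. After quantile normalization they were 0.21 for sugar supply, 0.032 for embryo and aleurone markers and 0.023 for green tissue markers, and with the title number as a block 0.022 for sugar supply. Without single arrays they ranged from -0.077 to 0.11 for sugar supply (positive without wild type replicate 2, osbzip58-1 replicate 1 or osbzip58-1 replicate 3), from -0.25 to 0.21 for embryo and aleurone markers (positive without wild type replicate 2 or osbzip58-1 replicate 1) and from -0.20 to 0.015 for green tissue markers (positive without wild type replicate 3). The cause was not tested. With the reporter probe sets tested as well, 2208 of 34923 changed and MCM5 had an adjusted p of 0.05, not past the threshold. With the replicate number as a block 1964 probe sets changed. The deviations of arrays with the same number correlated at 0.03, -0.03 and -0.02. These values give no sign that the numbers pair the samples, but they are too few to exclude it. Values near the floor limit the dimmest probe sets: those under a mean log2 signal of 6 gave 54 calls among 9202.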

Other observations

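The families below were called by tests chosen after array-level values were seen, their alternatives were all added after the results were seen, and the neighbour tests were chosen before their results were seen.

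Of the kinesins, the motor proteins of microtubules, 24 of 31 had a positive log2 fold change in osbzip58-1 and 7 a negative one. KIN14H rose from a log2 signal of 6.95 ± 0.14 to 8.84 ± 0.24 (SD, n = 3 per group), and KIN5C rose from 6.62 ± 0.40 to 8.35 ± 0.36, with limma adjusted p of 0.00185 and 0.00955. Of 31 measured kinesins 7 rose and 0 fell, with a median log2 fold change of 0.34 (camera adjusted p = 0.00310, and 0.461 with an estimated correlation; fry adjusted p = 0.00984). Expansins, which loosen cell walls, had a median of 0.44, with 5 of 22 up and 0 down (camera adjusted p = 0.00670, and 0.474 with an estimated correlation), and did not pass fry (adjusted p = 0.0714). EXP5 rose by 1.26 and EXLA3 by 0.95 on the log2 scale. DNA replication factors had a median of 0.67, with 5 of 19 up and 0 down (camera adjusted p = 0.000492, and 0.474 with an estimated correlation), and did not pass fry (adjusted p = 0.0510); 4 of the 5 were the MCM genes named above, and the other was RFC4 at 0.67. Kinesins and expansins no longer passed camera under spiked control scaling (adjusted p = 0.0509 and 0.260), and expansins did not without the filter (0.0837).

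Ribosomal proteins had a median of -0.19, with 0 of 25 up and 6 down, among them RPS7 at -0.78 and RPS4 at -0.72 (camera adjusted p = 1.35e-05, and 0.474 with an estimated correlation). They did not pass fry (adjusted p = 0.0666), and the median lay at percentile 31.0 of random lists matched on signal, whose own median was -0.17. That median was -0.0096 after quantile normalization (adjusted p = 0.223) and 0.21 under spiked control scaling (adjusted p = 0.167). Small heat shock proteins had a median of -0.35, which was -0.13 after quantile normalization (adjusted p = 0.0601) and 0.05 under spiked control scaling, with 0 of 19 up and 7 down, among them HSP21.9 at -1.25 and HSP23.2 at -1.11 (camera adjusted p = 0.000448, and 0.474 with an estimated correlation). Thioredoxins and glutaredoxins had a median of -0.10 as reported and 0.30 under spiked control scaling, with 2 of 28 down (camera adjusted p = 0.0277, and 0.461 with an estimated correlation), a call that ended without the filter (0.0505), after quantile normalization (0.132), with the title number as a block (0.0898), under spiked control scaling (0.791), without wild type replicate 3 (0.0544) and without osbzip58-1 replicate 3 (0.111). Small heat shock proteins and thioredoxins and glutaredoxins did not pass fry either (adjusted p = 0.0666 for each), and their medians lay at percentiles 0.55 and 11.6 of the matched lists, where kinesins, expansins and DNA replication factors lay at 99.85, 100 and 100. Of 29 families 6 passed camera and 0 passed with an estimated correlation; kinesins alone of the 6 passed fry as well.

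A chromosome segment that differs between the lines was tested as a source of changed genes that lie side by side. Of 16099 genes in chromosome order 1430 changed, in 145 neighbouring pairs, against a median of 127 in 10000 shuffles and an upper limit, fixed beforehand, of 147 (permutation p = 0.0466). Genes with a log2 fold change of 1 or more made 16 pairs, 12 of them in the same direction, against an upper limit of 15 (permutation p = 0.0130, and 0.0260 adjusted over both tests). The shuffles place calls on genes at random, so neighbours that change together for other reasons would add pairs too. The tests also fall on either side of their bound, so they leave the question open. Around LOC4342570, 5 of the 40 nearest measured genes changed, and 28.9% of windows of this size held as many or more (upper limit 8). The window thus held no unusual number of changed genes. How many a differing segment would add is not known, so this count cannot exclude such a segment.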
